A study of Mus musculus with 12 samples.

How the data were processed

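Whole-kidney RNA from 12 mouse samples had been hybridised to Affymetrix Clariom S arrays as biotinylated single-stranded DNA, per the labels' protocols. The deposited table holds 1 log2 value per probe set and sample, for 22206 probe sets and with no missing value. That the deposited values are on a log2 scale was read from the values, which run from 2.3 to 19.88 with similar quartiles in every sample. Transcriptome Analysis Console 4.0 is named per the submitters' processing notes. The background correction, the normalization between arrays and the way probes were summarised are not given in the sources used here. The values are not centred per probe set, and differences between samples were therefore taken as log2 changes.

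Probe sets were named through the platform annotation supplied with the series, updated through Entrez gene identifiers against a RefSeq gene table of assembly GRCm38.p6. That assembly served only for names and for which genes neighbour each other. A single gene symbol was found for 19572 probe sets, covering 19505 distinct symbols, and 2634 probe sets stayed unnamed. For 55 symbols there was more than 1 probe set, and tests of gene lists used the probe set with the highest mean over all samples. All 22206 probe sets entered the tests of single genes. Near-identical genes such as Cyp4a12a and Cyp4a12b, the Ces1 family, C4a and C4b and the H2 genes can share signal on an array, and their separate values are uncertain. Ren1 was not analysed here.

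Samples were grouped by their titles into wild type with vehicle and Alport with vehicle, losartan or metformin, with 3 samples in each group. A linear model with a mean per group was fitted to the log2 values of all 12 samples with limma 3.58.1 (lmFit and eBayes, R 4.3.3), which left 8 residual degrees of freedom. Tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method over the probe sets of each comparison, and an adjusted p under 0.05 counted as a change. Only for a change called in this way are the verbs rose, fell and changed used. Errors of log2 changes are standard errors from this model. The design, the tests, the lists of genes, the rule for named genes and the alternatives were fixed before the data were examined. The exceptions are the tests of the other Ces1 genes, of the neighbours of Ces1g and of male-biased and female-biased genes, which were chosen, with the genes they cover, after the result was seen.

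In total 37 lists of genes for pathways and for cell types of the kidney and its surroundings, each with at least 5 measured members, were tested with camera of limma. The preset correlation between genes was 0.01, and p-values were adjusted over the 37 lists. The same test was run with a correlation estimated from the data for each list. Genes were named by rule. A fixed set (Col4a5, Havcr1, Lcn2, Col1a1, Acta2, Tgfb1, Nphs1, Umod and Slc34a1, besides Ren1 and others not reported here) is followed through every comparison. In addition come up to 10 of the largest rises and 10 of the largest falls per comparison among called genes whose groups of 3 samples did not overlap, which chance alone gives in 10% of genes. From each described list come up to 4 members with the smallest p, and for a list of another cell type the member with the highest mean.

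Both drug comparisons share the Alport vehicle samples, with each other and with the comparison of Alport and wild type. Covariances and overlaps of calls were therefore set beside 100 simulations of unchanged groups that share these samples. The alternatives were centring each sample on its median, a new quantile normalization, leaving out the dimmest 33.3% of probe sets, a variance prior with trend and robust options, array weights, a fit of only the groups compared, an unadjusted p with a change of at least 2-fold, the estimated correlation for lists, a block for the replicate number and leaving out each sample in turn.

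The procedure was tested on simulated data with 22206 probe sets, of which 200 were changed by known amounts. For the comparison of Alport and wild type 4% of the genes changed by 0.5 on the log2 scale were called, 78% of those changed by 1 and 100% of those changed by 2 or 3. For losartan against vehicle the shares called at 0.5 and 1 were 6% and 78%, for metformin against vehicle 2% and 80%, and for metformin against losartan 6% and 84%. Over 20 draws the mean share of false calls was 6.14%, 5.93%, 5.63% and 5.59% in these 4 comparisons. The 1 shifted list among 20 simulated ones was called in each comparison, with 0 of the other lists. The simulated genes varied independently of each other, so this does not test lists whose genes vary together. In the samples the estimated correlation reached 0.659, for the macrophage list.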

Results

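Kidney transcript levels were measured on Affymetrix Clariom S arrays in 12 mouse samples of 4 groups, with 3 samples in each group. The groups were wild type mice given vehicle and Alport mice given vehicle, losartan or metformin. The Alport mice carried a hemizygous nonsense mutation of Col4a5, which encodes a type IV collagen chain of the glomerular basement membrane. Losartan blocks the angiotensin II receptor, and metformin is a biguanide that lowers blood glucose. Both drugs were given in drinking water, losartan at 125 and later 250 µg/mL and metformin at 2.5 and later 5 mg/mL, and the stated age of all mice was 16 weeks. The labels date the later dose from week 12 to week 20, past that age, and call losartan co-administered, so the groups are named here by the drug in the sample titles.

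The median log2 value was 5.88, 5.92 and 5.89 in the wild type samples, 6.05, 5.99 and 6.065 with Alport vehicle, 5.94, 5.94 and 5.95 with losartan, and 5.99, 5.96 and 5.94 with metformin. The Y-linked genes Kdm5d, Eif2s3y and Uty were measured in all 12 samples, at log2 5.73 to 6.67, 9.0 to 10.6 and 8.29 to 9.83. Pearson correlations across probe sets, which are not independent replicates, ran from 0.990 to 0.994 within groups and from 0.975 to 0.993 between groups. The labels do not say that the samples came from separate mice, so p-values measure the spread between these samples, which may be technical in part. The number of arrays limits the precision, and the median standard error of a log2 change was 0.20.

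The mutated gene was examined first. Col4a5 read 5.06, 5.83 and 5.40 on the log2 scale in the wild type samples, 4.44, 4.13 and 4.97 with Alport vehicle, 4.64, 4.24 and 4.09 with losartan and 4.48, 4.48 and 4.50 with metformin. It fell by 0.92 ± 0.23 (SE, n = 3 per group) in Alport vehicle against wild type (limma, Benjamini-Hochberg adjusted p = 0.0116). The adjusted p was 0.0663 without wild type sample 2 and 0.0519 without Alport vehicle sample 2. The signal of Col4a5 was low, since even its wild type values lay below the median of every sample. In Alport vehicle sample 2 (4.13) and losartan sample 3 (4.09) it lay below the lower quartile of that sample (4.23 and 4.25). The size of the fall is therefore uncertain.

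The comparison of vehicle-treated Alport and wild type kidneys asks what the mutation changed at this age. The lists of tubular injury, interstitial matrix and macrophage genes were shifted up in Alport kidneys, and the list of proximal tubule genes down. Of these only interstitial matrix held with an estimated correlation, with adjusted p = 0.0887, 0.0999 and 0.0883 with an estimated correlation for tubular injury, macrophages and the proximal tubule. Lcn2, a siderophore-binding protein released by injured tubules, rose 529-fold (log2 9.05 ± 0.68, limma adjusted p = 5.21e-07), and the injury receptor Havcr1 rose 197-fold (7.62 ± 0.56, limma adjusted p = 4.59e-07), or 125-fold without Alport vehicle sample 1. The collagen gene Col3a1 rose 69.7-fold and the lysozyme gene Lyz2, of macrophages, 79.2-fold. The fibrinogen gene Fgg, the adhesion molecule Vcam1, Col1a1 and the matrix genes Tnc and Mgp rose 49.2-, 45.0-, 42.3-, 32.2- and 31.1-fold. The wild type values of Col1a1 (5.42, 5.78 and 5.52) lay below the median of every sample, and those of Lcn2 (6.05, 6.20 and 6.02) near it. The sizes of these folds are therefore uncertain. The metalloproteinase inhibitor Timp1 rose too, to a mean of 9.17, but its wild type mean of 3.66 lay below the lower quartile of every sample, so no fold is given.

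The largest fall was that of Cyp4a12a, a fatty acid hydroxylase of the male mouse kidney, at log2 -3.997 ± 0.33 (limma adjusted p = 1.22e-06). Hrg, Pm20d1, the organic anion transporter Slco1a1, Fcamr, Azgp1, Dnase1, Pzp, Hpd and Tc2n had log2 changes from -3.91 to -2.78. That the 3 samples of each group did not overlap in these genes was a condition for naming them, and is no further support. Of the other genes fixed for every comparison, Acta2 of smooth muscle and myofibroblasts rose 11.6-fold and Tgfb1 rose 4.57-fold. Slc34a1, the phosphate carrier of the proximal tubule, fell by 0.56 ± 0.15 (limma adjusted p = 0.0169), with adjusted p-values of 0.0543 without wild type sample 1, 0.0749 without Alport vehicle sample 3, 0.0528 in a fit of only these groups and 0.0513 after a new quantile normalization. The slit diaphragm gene Nphs1 (log2 change -0.26 ± 0.20, limma adjusted p = 0.469) and Umod of the thick ascending limb (0.23 ± 0.15, limma adjusted p = 0.346) did not pass the test.

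**Figure D1:**
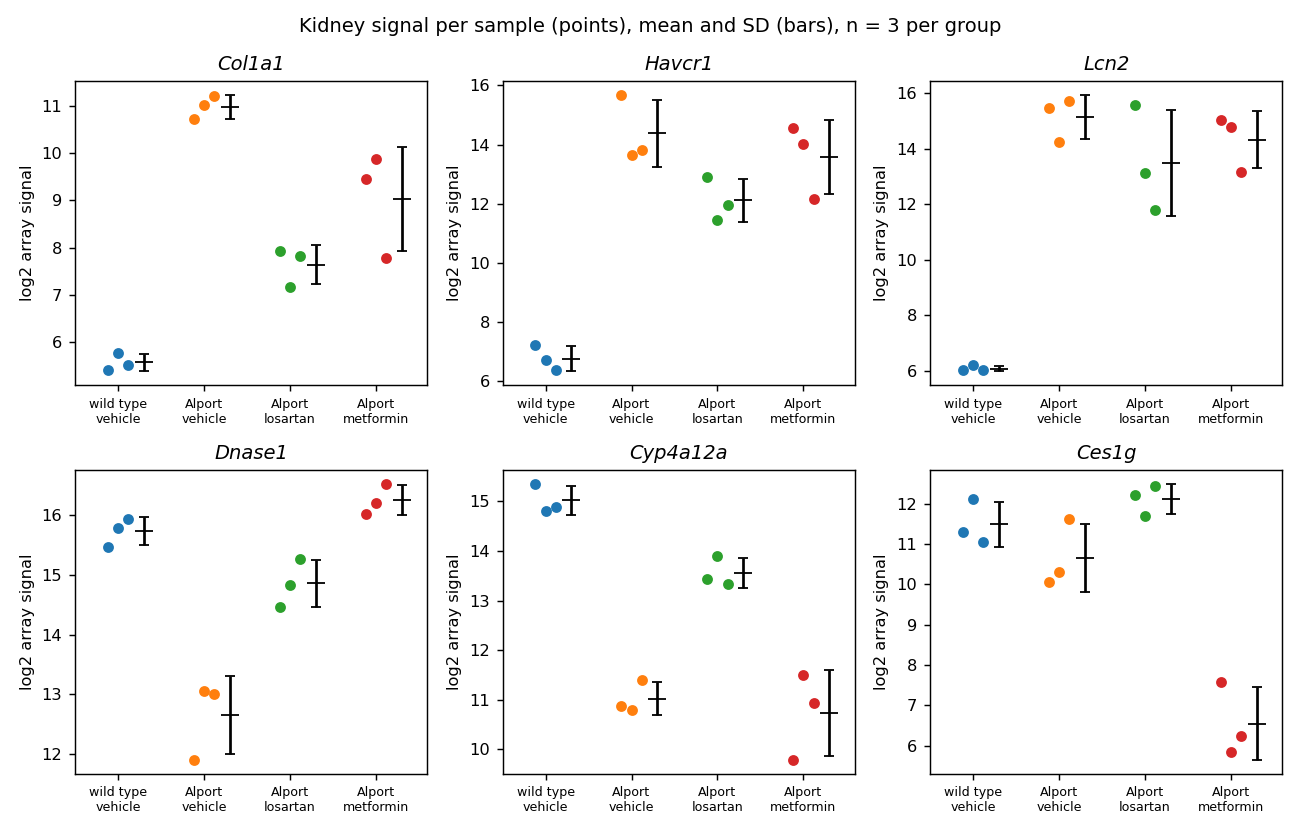
Log2 expression of Col1a1, Havcr1, Lcn2, Dnase1, Cyp4a12a and Ces1g in each of the 12 samples by group, with the mean and SD of the 3 samples. Col1a1 averaged 5.57 in wild type, 10.98 with Alport vehicle, 7.63 with losartan and 9.04 with metformin, and Ces1g lay at 7.57 or lower in the metformin samples and at 10.07 or higher in the other 9.

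Among the lists, 24 of 37 were shifted in Alport vehicle against wild type, 16 up and 8 down (camera with the preset correlation). Only fibrosis and interstitial matrix, podocyte and immediate early genes held with an estimated correlation. Of 33 measured genes of fibrosis and interstitial matrix, 32 rose (32 adjusted over the list alone), with a median log2 change of 2.51. For fibrosis and interstitial matrix camera gave an adjusted p of 3.59e-43, and adjusted p = 0.0364 with an estimated correlation. They included Col3a1 (6.12 ± 0.32), the proteoglycan Dcn (3.78 ± 0.22), Col1a2 (4.83 ± 0.31) and the contractile gene Tagln (3.51 ± 0.24). In the basement membrane list 10 of 20 rose and 2 fell (11 and 2 adjusted over the list alone), with Col4a1 at 1.52 ± 0.17, Col18a1 at 2.10 ± 0.23 and Nid1 at 1.61 ± 0.19. For the basement membrane list camera gave an adjusted p of 3.64e-05, and adjusted p = 0.109 with an estimated correlation. Of 21 podocyte genes 10 rose (11 adjusted over the list alone), among them Synpo (1.68 ± 0.17) and Nes (1.78 ± 0.26), while Clic5, the brightest of the list, was at -0.01 ± 0.15 and did not pass. The podocyte list had a camera adjusted p of 1.33e-06, and adjusted p = 0.0322 with an estimated correlation. Of 12 genes of pericytes and smooth muscle 5 rose (5 adjusted over the list alone), led by the receptor Pdgfrb at 2.04 ± 0.23. For pericytes and smooth muscle camera gave an adjusted p of 9.07e-05, and adjusted p = 0.0827 with an estimated correlation.

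Of 27 tubular injury genes 23 rose (23 adjusted over the list alone), with Anxa2 at 3.23 ± 0.29 beside Havcr1 and Lcn2. For tubular injury genes camera gave an adjusted p of 1.11e-20, and adjusted p = 0.0887 with an estimated correlation. Of 32 cytokines and chemokines 20 rose (23 adjusted over the list alone), with the monocyte attractant Ccl2 at 3.95 ± 0.40 and Cxcl16 at 2.03 ± 0.23. For cytokines and chemokines camera gave an adjusted p of 6.16e-17, and adjusted p = 0.0827 with an estimated correlation. Of 23 macrophage genes 19 rose (22 adjusted over the list alone), such as C1qc (2.82 ± 0.32), Fcer1g (2.22 ± 0.26), the mannose receptor Mrc1 (3.74 ± 0.46, and 4.40 without Alport vehicle sample 2) and Laptm5 (2.55 ± 0.35), with camera adjusted p = 1.48e-20 and adjusted p = 0.0999 with an estimated correlation. For MHC class II 6 of 9 genes rose (8 adjusted over the list alone), with H2-Eb1 at 2.85 ± 0.39 and H2-DMb1 at 2.22 ± 0.30. For MHC class II camera gave an adjusted p of 4.83e-07, and adjusted p = 0.109 with an estimated correlation. Of 28 interferon response genes 14 rose (18 adjusted over the list alone), including Gbp3 (1.82 ± 0.30) and Ifit3 (1.63 ± 0.28), with camera adjusted p = 1.01e-09 and adjusted p = 0.0999 with an estimated correlation. The complement list had 12 of 16 rising (13 rising and 1 falling adjusted over the list alone), with the inhibitor Serping1 at 3.29 ± 0.27 and C7 at 3.48 ± 0.31. For the complement list camera gave an adjusted p of 2.78e-11, and adjusted p = 0.109 with an estimated correlation. Of 21 T cell and NK cell genes 5 rose (5 adjusted over the list alone), among them Il7r (1.40 ± 0.27), Cd3e (1.22 ± 0.26) and Cd4 (0.93 ± 0.22), at camera adjusted p = 0.000842 and adjusted p = 0.109 with an estimated correlation. The neutrophil list did not pass (camera adjusted p = 0.409, median log2 change 0.02).

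Of 26 cell cycle genes 24 rose (24 adjusted over the list alone), with the mitotic cyclin Ccnb2 at 2.68 ± 0.23 and the proliferation marker Mki67 at 3.28 ± 0.29. For cell cycle genes camera gave an adjusted p of 4.41e-21, and adjusted p = 0.0567 with an estimated correlation. Of 17 immediate early genes 10 rose (11 rising and 1 falling adjusted over the list alone), with Egr1 at 3.92 ± 0.34 and Junb at 1.74 ± 0.24. For immediate early genes camera gave an adjusted p of 3.32e-08, and adjusted p = 0.0446 with an estimated correlation. In the list of ATF4 targets and the integrated stress response 10 of 26 rose and 1 fell (12 and 1 adjusted over the list alone), with the stress regulator Nupr1 at 3.96 ± 0.19 and the mitochondrial folate enzyme Shmt2 at -1.27 ± 0.17. For the ATF4 list camera gave an adjusted p of 0.000167, and adjusted p = 0.0887 with an estimated correlation.

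Proximal tubule genes went the other way. Of 38 measured, 29 fell (31 adjusted over the list alone), with a median log2 change of -0.85 (camera adjusted p = 1.5e-17, and adjusted p = 0.0883 with an estimated correlation). The transcription factor Hnf4a was at -1.31 ± 0.16 and the transporters Slc6a20b, Slc7a13 and Slc5a8 at -1.42 ± 0.18, -1.83 ± 0.24 and -1.35 ± 0.18, while Kap did not pass (-0.12 ± 0.14, limma adjusted p = 0.645). Its wild type mean of 19.63 was near the highest value on the arrays (19.88), so this does not show that it stayed level. Fatty acid oxidation had 15 of 30 genes falling (18 falling and 1 rising adjusted over the list alone), among them the carnitine transferase Cpt1a (-0.91 ± 0.15) and the nuclear receptor Ppara (-1.62 ± 0.28), with camera adjusted p = 1.17e-06 and adjusted p = 0.161 with an estimated correlation. Of 21 genes of the tricarboxylic acid cycle 10 fell (12 adjusted over the list alone), with pyruvate carboxylase Pcx at -1.52 ± 0.20 and Pdha1 at -1.09 ± 0.22. For the tricarboxylic acid cycle camera gave an adjusted p of 5.58e-06, and adjusted p = 0.181 with an estimated correlation. Of 19 cholesterol biosynthesis genes 12 fell (13 adjusted over the list alone), with the sterol sensor Insig1 at -1.42 ± 0.24 and Cyp51 at -1.60 ± 0.29. For cholesterol biosynthesis camera gave an adjusted p of 5.22e-08, and adjusted p = 0.109 with an estimated correlation. Of 15 intercalated cell genes 6 fell (8 falling and 1 rising adjusted over the list alone), with Insrr at -1.79 ± 0.23 and the anion exchanger Slc4a9 at -1.11 ± 0.18. For intercalated cell genes camera gave an adjusted p of 0.00169, and adjusted p = 0.109 with an estimated correlation. In the thick ascending limb list 1 gene rose and 1 fell of 13 (1 and 1 adjusted over the list alone), Cldn19 at 1.17 ± 0.19 and Egf at -2.03 ± 0.33, and the list did not pass (camera adjusted p = 0.842).

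In this comparison 3582 of 22206 probe sets changed, 1871 up and 1711 down. After centring each sample on its median, which moved the median log2 change of all probe sets from -0.03 to -0.17, 4293 changed, 1451 up and 2842 down.

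**Figure D2:**
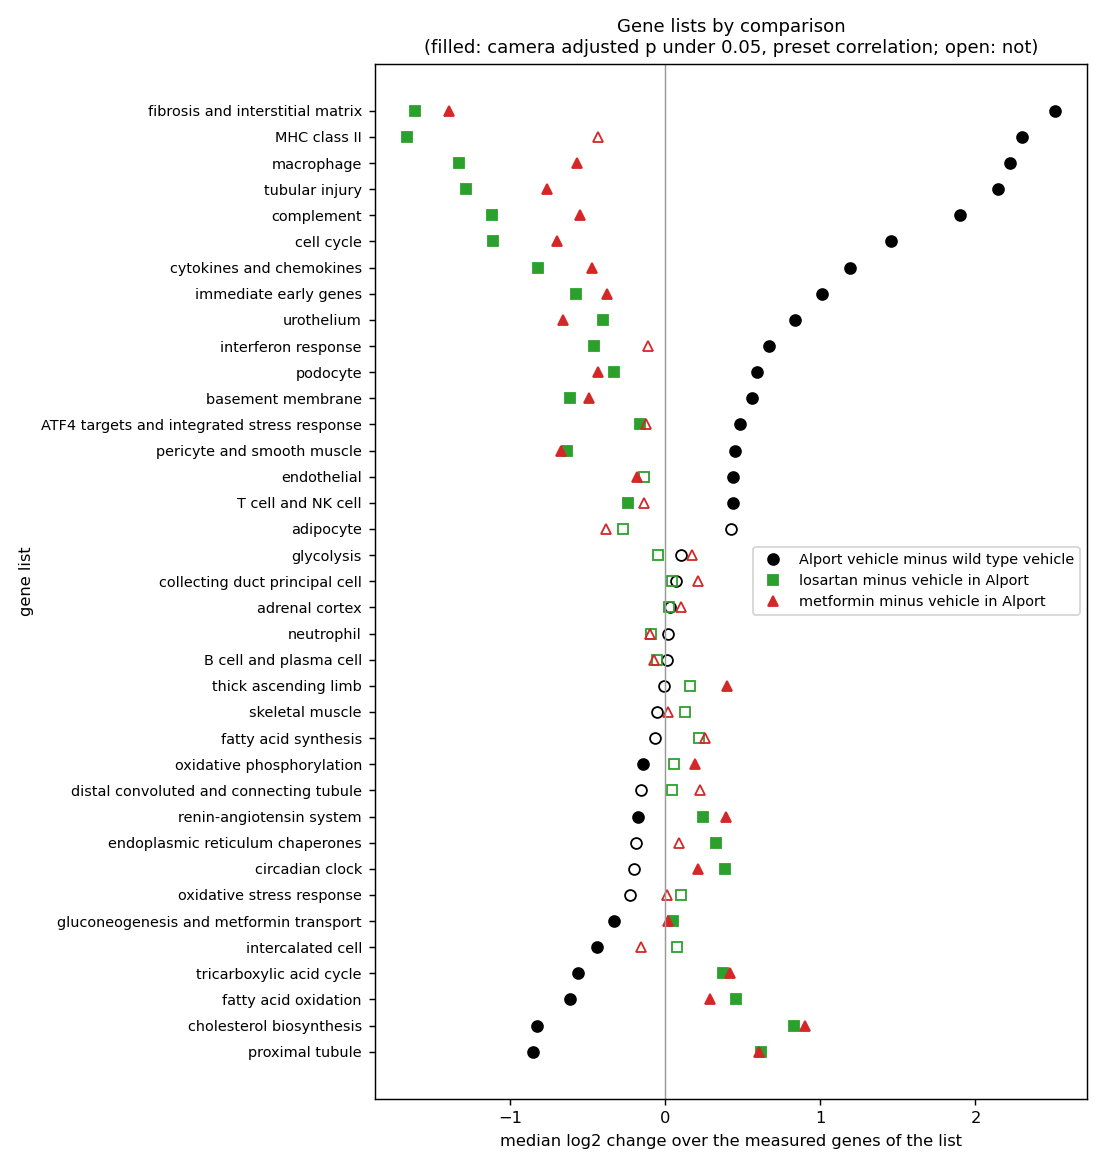
Median log2 change over the measured genes of each of the 37 lists in Alport vehicle against wild type (circles), losartan against Alport vehicle (squares) and metformin against Alport vehicle (triangles). Filled symbols passed camera with the preset correlation at an adjusted p under 0.05 (24, 23 and 21 lists), and open symbols did not.

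The comparison of losartan with vehicle in Alport kidneys asks what angiotensin receptor blockade changed. The lists of interstitial matrix and of cytokines and chemokines were shifted down with losartan, and that of the proximal tubule up, though not with an estimated correlation. Col1a1 fell 10.1-fold (log2 -3.34 ± 0.38, limma adjusted p = 0.000254), Col3a1 8.34-fold, the monocyte attractant Ccl2 8.21-fold and the immunoglobulin joining chain Jchain 8.0-fold. Timp1, Col1a2, Lyz2, Vcam1 and Tnc fell 7.94-, 7.69-, 7.19-, 6.16- and 5.78-fold, and the hyaluronan receptor Cd44 6.73-fold (limma adjusted p = 0.00749, and 0.0511 with a trended robust prior). The largest rises were those of Azgp1 at 6.31-fold (2.66 ± 0.33, limma adjusted p = 0.000437), Slco1a1 at 5.91-fold and Cyp4a12a at 5.79-fold, genes that were among the largest falls in Alport vehicle.

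Slc22a19, Hpd, Hrg, Pm20d1 and Fcamr rose 5.64-, 5.40-, 5.38-, 5.12- and 5.03-fold with losartan, and Slc22a7 5.46-fold (limma adjusted p = 0.00882, and 0.0678 with a trended robust prior), or 3.18-fold without Alport vehicle sample 1. The lipid transporter Mfsd2a rose 4.80-fold (limma adjusted p = 0.0216), with adjusted p-values of 0.115 without Alport vehicle sample 1, 0.0567 and 0.105 without losartan samples 1 and 2, and 0.109 with a trended robust prior. Acta2 fell 4.35-fold. Tgfb1 fell 2.67-fold (limma adjusted p = 0.00777, and 0.0507 without losartan sample 2), and Havcr1 fell 4.82-fold (limma adjusted p = 0.021). That call of Havcr1 was lost without Alport vehicle sample 1 (3.07-fold, adjusted p = 0.116), losartan sample 2 (0.109) or losartan sample 3 (0.0699), and with a trended robust prior (0.121). Lcn2 (-1.64 ± 0.68, limma adjusted p = 0.172), Slc34a1 (0.31 ± 0.15, 0.264), Umod (-0.06 ± 0.15, 0.890), Nphs1 (0.00 ± 0.20) and Col4a5 (-0.19 ± 0.23, 0.725) did not pass the test. Without losartan sample 1 Lcn2 passed (-2.67, adjusted p = 0.00777), and without losartan sample 3 it was at -0.80 (0.564).

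With losartan 23 of the 37 lists were shifted, 8 up and 15 down (camera with the preset correlation), and 0 held with an estimated correlation. Of 33 genes of fibrosis and interstitial matrix 31 fell (31 adjusted over the list alone), with the collagen cross-linker Lox at -2.28 ± 0.28 beside the collagens. For fibrosis and interstitial matrix camera gave an adjusted p of 3.8e-39, and adjusted p = 0.0553 with an estimated correlation. The basement membrane list had 9 of 20 falling (11 adjusted over the list alone), with Nid1 at -1.36 ± 0.19 and Hspg2 at -1.09 ± 0.18. For the basement membrane list camera gave an adjusted p of 3.42e-08, and adjusted p = 0.0843 with an estimated correlation. Pericyte and smooth muscle genes fell in 5 of 12 cases (7 adjusted over the list alone), led by Pdgfrb at -1.60 ± 0.23. For pericytes and smooth muscle camera gave an adjusted p of 3.36e-07, and adjusted p = 0.0553 with an estimated correlation. Of 27 tubular injury genes 17 fell (22 adjusted over the list alone), with S100a6 at -1.95 ± 0.30 and the transcription factor Sox9 at -2.15 ± 0.36. For tubular injury genes camera gave an adjusted p of 2.37e-16, and adjusted p = 0.134 with an estimated correlation. Of 26 cell cycle genes 17 fell (21 adjusted over the list alone), with Mki67 at -2.50 ± 0.29 and the checkpoint kinase Bub1b falling to a mean of 4.05, below the lower quartile of every sample. For cell cycle genes camera gave an adjusted p of 3.9e-20, and adjusted p = 0.0642 with an estimated correlation. Of 17 immediate early genes 8 fell (11 falling and 1 rising adjusted over the list alone), with Egr1 at -2.53 ± 0.34 and Ccn1 at -1.58 ± 0.27. For immediate early genes camera gave an adjusted p of 1.07e-07, and adjusted p = 0.0553 with an estimated correlation.

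Of 32 cytokines and chemokines 15 fell with losartan (20 adjusted over the list alone), with Cxcl16 at -1.41 ± 0.23 and Cxcl10 at -2.05 ± 0.35. For cytokines and chemokines camera gave an adjusted p of 1.84e-13, and adjusted p = 0.0955 with an estimated correlation. Of 23 macrophage genes 13 fell (20 adjusted over the list alone), such as Mrc1 at -2.34 ± 0.46 (-3.00 without Alport vehicle sample 2) and Fcer1g at -1.31 ± 0.26. For macrophage genes camera gave an adjusted p of 3.22e-15, and adjusted p = 0.154 with an estimated correlation. For MHC class II 5 of 9 fell (6 adjusted over the list alone), with H2-Eb1 at -1.89 ± 0.39 and H2-DMb1 at -1.46 ± 0.30. For MHC class II camera gave an adjusted p of 1.09e-06, and adjusted p = 0.154 with an estimated correlation. Interferon response genes fell in 3 of 28 cases (7 adjusted over the list alone), with Irf1 at -1.34 ± 0.28 and Bst2 at -1.16 ± 0.24. For the interferon response camera gave an adjusted p of 2.91e-06, and adjusted p = 0.154 with an estimated correlation. Of 16 complement genes 8 fell (10 adjusted over the list alone), with Serping1 at -1.88 ± 0.27 and C7 at -1.54 ± 0.31. For the complement list camera gave an adjusted p of 2.04e-08, and adjusted p = 0.154 with an estimated correlation.

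Proximal tubule genes rose with losartan in 17 of 38 cases (26 adjusted over the list alone), with Hnf4a at 1.22 ± 0.16, Slc7a13 at 1.77 ± 0.24 and Slc6a20b at 1.28 ± 0.18. For proximal tubule genes camera gave an adjusted p of 1.09e-17, and adjusted p = 0.0843 with an estimated correlation. Of 30 fatty acid oxidation genes 10 rose and 1 fell (13 and 1 adjusted over the list alone), with the acyl-CoA dehydrogenase Acadm at 1.09 ± 0.22. For fatty acid oxidation camera gave an adjusted p of 3.61e-07, and adjusted p = 0.154 with an estimated correlation. The tricarboxylic acid cycle list had 6 of 21 rising (10 adjusted over the list alone), with Pcx at 1.09 ± 0.20 and Pdha1 at 1.12 ± 0.22. For the tricarboxylic acid cycle camera gave an adjusted p of 4.06e-07, and adjusted p = 0.154 with an estimated correlation. Of 19 cholesterol biosynthesis genes 11 rose (16 adjusted over the list alone), with Dhcr7 at 1.48 ± 0.21 and Sqle at 1.17 ± 0.20. For cholesterol biosynthesis camera gave an adjusted p of 5.35e-12, and adjusted p = 0.0955 with an estimated correlation. In the renin-angiotensin list, on which losartan acts, 2 of 13 rose (2 adjusted over the list alone), with Ace, which makes angiotensin II, at 1.12 ± 0.22. For the renin-angiotensin list camera gave an adjusted p of 0.0245, and adjusted p = 0.205 with an estimated correlation. This list lost its call without Alport vehicle sample 2 (camera adjusted p = 0.0839), losartan sample 2 (0.0701) or losartan sample 3 (0.0583), and after a new quantile normalization (0.0941). In Alport vehicle against wild type the same list was shifted down, with 5 of 13 falling (camera adjusted p = 0.0109, and adjusted p = 0.166 with an estimated correlation). After a new quantile normalization its camera adjusted p there was 0.0588.

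In all, 1755 probe sets changed with losartan, 842 up and 913 down, and after centring on sample medians 1962 changed, 1238 up and 724 down, with the median of all probe sets moving from 0.01 to 0.11. Without Alport vehicle sample 1 the count was 737, without losartan sample 2 it was 716, and without losartan sample 3 it was 959.

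The comparison of metformin with vehicle in Alport kidneys asks the same of metformin. The list of pericyte and smooth muscle genes was shifted down with metformin, also with an estimated correlation. Its median log2 change was -0.67, and -0.632 with losartan. Dnase1, a nuclease of the kidney tubule, rose 12.1-fold (log2 3.6 ± 0.28, limma adjusted p = 1.6e-05), and Car3, a carbonic anhydrase, 7.21-fold (10.8-fold without metformin sample 1). The carboxylesterase gene Ces1g fell 17.3-fold (-4.12 ± 0.43, limma adjusted p = 0.000174). Jchain fell 6.20-fold, Ccl2 5.29-fold, the transthyretin gene Ttr 4.97-fold and Tnc 4.28-fold.

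Other large rises with metformin were those of the transferrin receptor Tfrc (6.60-fold), Cyp2d12 (5.84-fold), Slc22a19 (5.09-fold), the clock gene Ciart (4.27-fold), Acsm1 (4.27-fold) and the fructose carrier Slc2a5 (4.26-fold). Hpd rose 4.17-fold (limma adjusted p = 0.0128, but 0.0564 without Alport vehicle sample 1 and 0.0727 without metformin sample 3). Mfsd2a rose 4.50-fold (limma adjusted p = 0.0385), and its adjusted p was 0.167 and 0.0733 without Alport vehicle samples 1 and 3, 0.124 and 0.0876 without metformin samples 2 and 3, 0.101 in a fit of only these groups, 0.144 with a trended robust prior and 0.0558 with array weights. Col1a2, Acta2, Egr1 and Col1a1 fell 4.24-, 4.11-, 4.04- and 3.84-fold, and Sfrp4 fell to a mean of 3.75, below the lower quartile of every sample. Without metformin sample 3 the fall of Col1a1 was 2.49-fold. Without metformin samples 1 and 2 the rise of Mfsd2a was 7.22- and 2.54-fold. Tgfb1 fell 2.35-fold (limma adjusted p = 0.0237), with 0.121 and 0.0734 without Alport vehicle samples 1 and 3, 0.0546 and 0.126 without metformin samples 2 and 3, and 0.0804 in a fit of only these groups. Havcr1 (-0.80 ± 0.56, limma adjusted p = 0.507), Lcn2 (-0.82 ± 0.68, 0.597), Slc34a1 (0.31 ± 0.15, 0.296), Umod (0.11 ± 0.15, 0.774), Nphs1 (-0.14 ± 0.20, 0.800) and Col4a5 (-0.03 ± 0.23, 0.977) did not pass. Havcr1 was at -0.153 without Alport vehicle sample 1 and -0.09 without metformin sample 3, and Lcn2 at -0.232 without metformin sample 3.

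With metformin 21 lists were shifted, 9 up and 12 down (camera with the preset correlation), and those of podocytes and of pericytes and smooth muscle held with an estimated correlation. Of 33 genes of fibrosis and interstitial matrix 23 fell (32 adjusted over the list alone), with Ccn2 at -1.62 ± 0.22, Tagln at -1.73 ± 0.24 and Dcn at -1.53 ± 0.22. For fibrosis and interstitial matrix camera gave an adjusted p of 1.87e-30, and adjusted p = 0.0659 with an estimated correlation. The basement membrane list had 5 of 20 falling (10 adjusted over the list alone), with Nid1 at -1.19 ± 0.19 and Hspg2 at -0.98 ± 0.18. For the basement membrane list camera gave an adjusted p of 6.96e-06, and adjusted p = 0.119 with an estimated correlation. Of 12 genes of pericytes and smooth muscle 5 fell (7 adjusted over the list alone), with calponin Cnn1 at -1.35 ± 0.21 and the smooth muscle myosin Myh11 at -1.22 ± 0.22. For pericytes and smooth muscle camera gave an adjusted p of 2.99e-08, and adjusted p = 0.0341 with an estimated correlation. In metformin minus losartan this list did not pass (median -0.045, camera adjusted p = 0.711). Podocyte genes fell in 5 of 21 cases (7 adjusted over the list alone), with the transcription factor Tcf21 at -1.55 ± 0.25, Thsd7a at -1.06 ± 0.19 and Sema3g at -1.37 ± 0.27. For podocyte genes camera gave an adjusted p of 1.96e-06, and adjusted p = 0.0324 with an estimated correlation. Their median was -0.433 with metformin. With losartan it was -0.33, with 1 of 21 falling (camera adjusted p = 0.00596, and adjusted p = 0.0843 with an estimated correlation). In metformin minus losartan it was -0.137, with 0 called (camera adjusted p = 0.004, and adjusted p = 0.226 with an estimated correlation). Of 17 immediate early genes 3 fell (5 adjusted over the list alone), which were Egr1 (-2.01 ± 0.34), Ccn1 (-1.54 ± 0.27) and Ier3 (-1.19 ± 0.22), with camera adjusted p = 0.000284 and adjusted p = 0.119 with an estimated correlation.

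Of 27 tubular injury genes 5 fell with metformin and 1 rose (14 and 1 adjusted over the list alone), with S100a11 at -1.11 ± 0.20 and a median log2 change of -0.76. The 1 that rose was Itgb6 at 0.78 ± 0.21, named after its values were seen. For tubular injury genes camera gave an adjusted p of 2.99e-08, and adjusted p = 0.26 with an estimated correlation. Of 26 cell cycle genes 11 fell (14 adjusted over the list alone), with Mki67 at -1.51 ± 0.29 (limma adjusted p = 0.00801, and 0.0501 in a fit of only these groups). For cell cycle genes camera gave an adjusted p of 2.56e-10, and adjusted p = 0.131 with an estimated correlation.

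Inflammatory lists held few called genes with metformin. Called or not, 22 of 23 macrophage genes (median -0.57) and 30 of 32 cytokines and chemokines (median -0.473) had a log2 change below 0. In the simulated data only 2% of changes of 0.5 were called in this comparison. Of 32 cytokines and chemokines 3 fell (9 adjusted over the list alone) beside a camera adjusted p of 6.61e-08, and adjusted p = 0.191 with an estimated correlation. Of 23 macrophage genes 1 fell (1 adjusted over the list alone), with camera adjusted p = 6.96e-06 and adjusted p = 0.337 with an estimated correlation. That gene was Mrc1 at -1.75 ± 0.46 (limma adjusted p = 0.0388), with adjusted p-values of 0.157 and 0.139 without Alport vehicle samples 1 and 3, 0.0676 and 0.182 without metformin samples 2 and 3, 0.129 in a fit of only these groups, 0.105 with a trended robust prior and 0.053 with array weights. Without Alport vehicle sample 2 it was at -2.41. The MHC class II list did not pass (0 of 9 genes called and 0 adjusted over the list alone, median log2 change -0.43, camera adjusted p = 0.0938), but its camera adjusted p was 0.0232 without Alport vehicle sample 2 and 0.000492 without metformin sample 1. Interferon response genes likewise did not pass (camera adjusted p = 0.242), but reached 0.00219 without metformin sample 1. Without metformin sample 3 the medians of these lists were -0.002 for MHC class II (camera adjusted p = 0.735) and 0.007 for the interferon response (0.765).

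Of 38 proximal tubule genes 12 rose with metformin (26 adjusted over the list alone), with Slc6a20b at 1.20 ± 0.18, Slc13a3 at 1.34 ± 0.23 and Slc5a8 at 1.05 ± 0.18. For proximal tubule genes camera gave an adjusted p of 1.08e-17, and adjusted p = 0.119 with an estimated correlation. Of 19 cholesterol biosynthesis genes 11 rose (14 adjusted over the list alone), with the squalene epoxidase Sqle at 1.69 ± 0.20, Dhcr7 at 1.45 ± 0.21 and Fdps at 1.14 ± 0.24. For cholesterol biosynthesis camera gave an adjusted p of 7.62e-12, and adjusted p = 0.119 with an estimated correlation. The tricarboxylic acid cycle list had 3 of 21 rising (10 adjusted over the list alone), with Pcx at 1.44 ± 0.20. For the tricarboxylic acid cycle camera gave an adjusted p of 1.79e-07, and adjusted p = 0.191 with an estimated correlation. In the list of gluconeogenesis and metformin transport 5 of 17 rose (7 adjusted over the list alone), with the glucose 6-phosphate carrier Slc37a4 at 1.41 ± 0.22 and the cation carrier Slc22a2, which takes up metformin, at 0.93 ± 0.18. For gluconeogenesis and metformin transport camera gave an adjusted p of 0.0107, and adjusted p = 0.191 with an estimated correlation. The camera adjusted p of that list was 0.0537 after a new quantile normalization, and its median log2 change with metformin was 0.02. It was also shifted up with losartan, with 4 of 17 rising (camera adjusted p = 0.00784, and adjusted p = 0.154 with an estimated correlation). In Alport vehicle against wild type 6 fell and 1 rose (camera adjusted p = 0.00429, and adjusted p = 0.109 with an estimated correlation). In metformin minus losartan it did not pass (median -0.007, camera adjusted p = 0.931). Renin-angiotensin genes rose in 3 of 13 cases (3 adjusted over the list alone), with Ace at 1.35 ± 0.22. For the renin-angiotensin list camera gave an adjusted p of 7.53e-05, and adjusted p = 0.119 with an estimated correlation. In metformin minus losartan its median was 0.15, with 0 called (camera adjusted p = 0.0399, and adjusted p = 0.352 with an estimated correlation). Without the dimmest probe sets the camera adjusted p of that difference was 0.123.

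In all, 1096 probe sets changed with metformin, 592 up and 504 down, and after centring on sample medians 1208 changed, 827 up and 381 down. The count was 347 and 728 without Alport vehicle samples 1 and 3, 647 and 266 without metformin samples 2 and 3, and 410 in a fit of only these groups.

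The direct comparison of metformin with losartan in Alport kidneys asks where the drugs differed. Ces1g was the largest difference, 47.7-fold lower with metformin (log2 -5.58 ± 0.43, limma adjusted p = 6.8e-06), followed by Cyp4a12a, 7.05-fold lower (-2.82 ± 0.33, limma adjusted p = 0.00146). Cyp4a12b was 3.40-fold lower and the annexin Anxa13 2.60-fold lower. Car3 was 6.82-fold higher with metformin (10.2-fold without metformin sample 1), the growth factor binding protein Igfbp1 2.69-fold, the sugar carrier Slc5a10 2.17-fold and the bile acid carrier Slc10a2 2.16-fold. These 8 named genes and 2 unnamed probe sets were all that changed of 22206, 4 up and 6 down, while 1859 had an unadjusted p under 0.05.

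Ces1g and Cyp4a12a kept their calls without any single sample. In a fit of only these groups the calls of the 6 other named genes were lost, with a limma adjusted p of 0.0687 for Car3 and Cyp4a12b, 0.0691 for Igfbp1, 0.107 for Slc5a10 and Anxa13 and 0.154 for Slc10a2. With a trended robust prior the adjusted p of Car3 was 0.074. The limma adjusted p of Car3 rose from 0.0116 to 0.0951 and 0.061 without losartan samples 1 and 2 and to 0.102 without metformin sample 2. For Igfbp1 it went from 0.0116 to 0.061 and 0.059 without losartan samples 2 and 3 and to 0.0808 without metformin sample 1. Slc5a10, at 0.0217, had 0.132 and 0.118 without losartan samples 1 and 2 and 0.161 and 0.123 without metformin samples 1 and 2. Slc10a2, at 0.0217, had 0.132, 0.133 and 0.0533 without losartan samples 1, 2 and 3 and 0.0509 without metformin sample 1. Anxa13, at 0.0185, had 0.116 and 0.133 without losartan samples 1 and 2 and 0.0648 and 0.116 without metformin samples 1 and 2. For Cyp4a12b the limma adjusted p was 0.00782, and 0.0509 without metformin sample 1.

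Among the fixed genes Col1a1 was at 1.40 ± 0.38 in metformin minus losartan (limma adjusted p = 0.298), Havcr1 at 1.47 ± 0.56 (0.493), Lcn2 at 0.83 ± 0.68 (0.817), Acta2 at 0.08 ± 0.32 (0.978) and Tgfb1 at 0.18 ± 0.29 (0.936), and none of these passed. Without metformin sample 3 Col1a1 passed (2.03, limma adjusted p = 0.00181). Without that sample Havcr1 was at 2.18 (0.0869) and Lcn2 at 1.41, and Lcn2 was at 1.855 and -0.02 without losartan samples 1 and 3. Camera with the preset correlation shifted 20 of 37 lists, 15 up and 5 down, and 0 held with an estimated correlation. The lists of macrophages (median log2 change 0.59, camera adjusted p = 7.87e-09, and adjusted p = 0.352 with an estimated correlation), MHC class II (1.09, camera adjusted p = 7.22e-07, and adjusted p = 0.227 with an estimated correlation) and cell cycle (0.45, camera adjusted p = 2.83e-09, and adjusted p = 0.227 with an estimated correlation) had higher medians with metformin. In these lists 0 members were called, with 0, 6 and 3 higher when adjusted over the list alone. Fibrosis and interstitial matrix (0.43, camera adjusted p = 1.93e-08, and adjusted p = 0.298 with an estimated correlation) was higher with metformin too. So was tubular injury (0.33, camera adjusted p = 1.98e-06, and adjusted p = 0.366 with an estimated correlation). These lists had 0 called members as well, with 2 and 1 higher when adjusted over the list alone. The proximal tubule list (median -0.04, camera adjusted p = 0.350, 0 called and 0 adjusted over the list alone) and the cholesterol biosynthesis list (-0.03, camera adjusted p = 0.930, 0 called and 0 adjusted over the list alone) did not pass. The count of 10 changed probe sets was 6 and 5 without losartan samples 1 and 2, 6 and 91 without metformin samples 1 and 3 (77 up and 14 down without sample 3), 3 in a fit of only these groups and 17 with array weights.

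Treated Alport kidneys were also set against wild type kidneys, to ask what difference was left. Lcn2 was 169-fold higher with losartan (log2 7.40 ± 0.68, limma adjusted p = 5.76e-05) and 300-fold higher with metformin (8.23 ± 0.68, limma adjusted p = 6.67e-06). Without losartan samples 1 and 3 Lcn2 was 83.0- and 304-fold higher with losartan, and without metformin sample 3 it was 450-fold higher with metformin. Havcr1 was 40.8-fold higher with losartan and 113-fold higher with metformin (185-fold without metformin sample 3). Col1a1 was 11.0-fold higher with metformin (limma adjusted p = 8.86e-05, and 17.0-fold without metformin sample 3) and 4.17-fold higher with losartan (limma adjusted p = 0.0221). The folds of Col1a1 and Lcn2 are uncertain in size, since their wild type signal was below or near the sample medians.

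That call of Col1a1 with losartan was lost without wild type samples 1, 2 or 3 (adjusted p = 0.0754, 0.0716 and 0.123) or losartan samples 1 or 3 (0.111 and 0.0939). Acta2 was 2.81-fold higher than wild type with metformin (limma adjusted p = 0.0156, but 0.0778 and 0.0731 without wild type samples 2 and 3 and 0.0906 without metformin sample 1), and did not pass with losartan (1.41 ± 0.32, limma adjusted p = 0.0654, but 0.0427 without wild type sample 1, 0.0396 in a fit of only these groups and 0.0243 with array weights). Tgfb1 did not pass with losartan (0.78 ± 0.29, limma adjusted p = 0.307) or metformin (0.96 ± 0.29, limma adjusted p = 0.0777, but 0.0192 without metformin sample 3 and 0.0433 with array weights). Col4a5 was lower than wild type with losartan (-1.11 ± 0.23, limma adjusted p = 0.044), with 0.177 and 0.17 without wild type samples 2 and 3 and 0.0624, 0.158 and 0.175 without losartan samples 1, 2 and 3. With metformin Col4a5 was at -0.94 ± 0.23 (limma adjusted p = 0.0307), with 0.134 and 0.0921 without wild type samples 2 and 3 and 0.101, 0.0904 and 0.055 without metformin samples 1, 2 and 3. Against wild type 122 probe sets changed in losartan kidneys, 89 up and 33 down, and 928 in metformin kidneys, 599 up and 329 down (513 up and 486 down of 999 after centring on sample medians).

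The count for losartan was 62, 38 and 37 without wild type samples 1, 2 and 3, 41, 55 and 60 without losartan samples 1, 2 and 3, 285 in a fit of only these groups and 195 with array weights. For metformin it was 576, 501 and 352 without wild type samples 1, 2 and 3, and 346 and 431 without metformin samples 1 and 2.

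Changes with either drug ran largely opposite to the Alport changes. Over all probe sets, called or not, the signs were opposite in 76.5% with losartan and 71.7% with metformin. Simulations of unchanged groups that share the Alport vehicle samples gave means of 66.7% and 66.6%. Of the 1755 probe sets called with losartan, 1503 (85.6%) were called the other way in Alport vehicle against wild type, with 812 up in Alport and down with losartan, such as Col1a1 and Ccl2, and 691 the other way round, such as Hnf4a and Azgp1. The overlap of independent calls would be 76.9 and 64.9. With metformin 866 of 1096 (79.0%) were called the other way, 404 up in Alport and down with metformin, such as Dcn and Egr1, and 462 the other way round, such as Dnase1 and Sqle, against 42.5 and 45.6 for independent calls. Losartan and metformin shared 730 calls in the same direction, 385 up and 345 down, against 22.4 and 20.7 for independent calls. Calls in the same direction as in Alport vehicle numbered 0 for losartan and 3 for metformin, and 1 probe set was called in opposite directions by the drugs. In 100 simulations of unchanged groups that share the Alport vehicle samples, the highest of these overlaps were 1, 0 and 1. Unchanged groups give almost no calls, so these values do not show how many of the shared calls come from the shared samples.

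**Figure D3:**
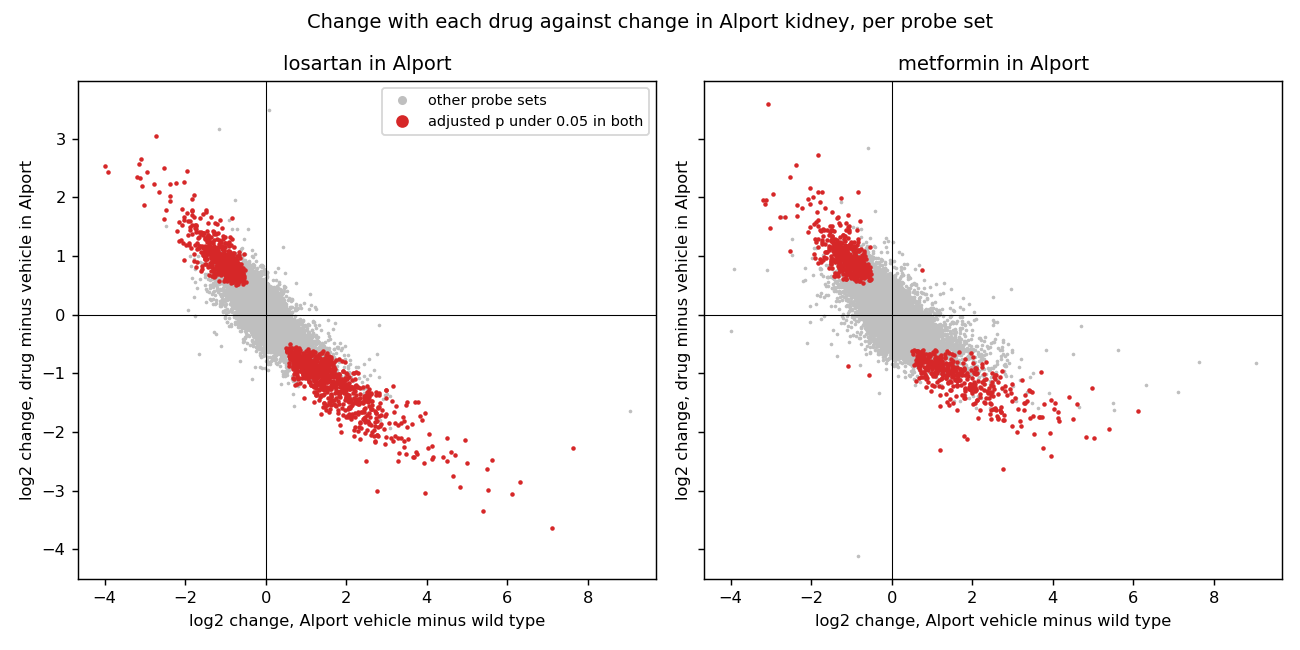
Log2 change with losartan and with metformin, each against Alport vehicle, plotted against the log2 change of Alport vehicle against wild type, per probe set. Red points were called in both comparisons, and for losartan 1503 of them lie in the quadrants of opposite sign and 0 in the others.

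Across probe sets, which are not independent, the covariance of the log2 changes in Alport and with losartan was -0.212, against a simulated mean of -0.0228 for unchanged groups that share the vehicle samples, a difference of -0.19. Their correlation was -0.851, and -0.500 in the simulations. For metformin the covariance was -0.160 and the simulated mean -0.0227, a difference of -0.138, with correlations of -0.720 and -0.500. For losartan and metformin together the covariance was 0.127 and the simulated mean 0.0227, a difference of 0.104, with correlations of 0.781 and 0.499. With different vehicle samples on each side, so that no sample was shared, the covariance ran from -0.200 to -0.142 for losartan, from -0.151 to -0.0847 for metformin and from 0.0718 to 0.113 for the drugs together. The 3 vehicle samples are too few to split for the overlaps of calls, and part of their excess over independent calls may come from the shared samples. The count of 1503 was 664 without Alport vehicle sample 1 and 673 and 868 without losartan samples 2 and 3, and the count of 866 was 282 without Alport vehicle sample 1 and 543 and 238 without metformin samples 2 and 3. The count of 730 was 226 and 475 without Alport vehicle samples 1 and 3, 413 and 465 without losartan samples 2 and 3, and 458 and 222 without metformin samples 2 and 3.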

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

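All alternatives were planned, and none was chosen after the results were seen. Of 378 called results of named genes, 244 kept their call and direction in every alternative, and 0 reversed. Over all alternatives, values of named genes stayed on the same side of the threshold in 4743 cases, lost a call in 543, gained one in 7 and changed direction in 19, which were all uncalled. Single lists kept their side in 1292 cases, lost a call in 132, gained one in 6 and turned in 10, and counts stayed within 1.5 times the main value in 136 cases and left that range in 49. Removing a sample leaves a group of 2, and the number of calls was lower in most cases. The smaller group alone does not account for this. With metformin the count was 897 without metformin sample 1, 266 without sample 3 and 1320 without Alport vehicle sample 2. Over all probe sets, the SD of the difference from wild type samples was 0.44 to 0.45 for metformin sample 3. It was 0.51 to 0.59 for metformin samples 1 and 2. For Alport vehicle sample 2 it was 0.56 to 0.60, and for samples 1 and 3 0.69 to 0.73. Whether this sets the counts was not tested. The spread between arrays limits small changes, since the share of simulated changes of 0.5 on the log2 scale that was called was 2% to 6%.

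With an unadjusted p and a change of at least 2-fold, 1565 probe sets passed in Alport vehicle against wild type, 799 with losartan, 511 with metformin, 102 in metformin against losartan (78 up and 24 down), 239 in losartan against wild type and 542 in metformin against wild type. A fit of only the groups compared, with fewer residual degrees of freedom, called 410 with metformin, 3 in metformin against losartan and 285 in losartan against wild type. Array weights, which ran from 0.712 to 1.21, gave 17 in metformin against losartan and 195 in losartan against wild type, and the cause was not tested. The estimated correlation left 3 lists for Alport vehicle, 0 for losartan, 2 for metformin and 0 for metformin against losartan, where the correlation estimated for fibrosis and interstitial matrix in Alport vehicle, for example, was 0.37.

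Without a single sample, the lowest and highest counts were 716 and 2073 for losartan, 266 and 1320 for metformin, 5 and 91 for metformin against losartan, 37 and 62 for losartan against wild type and 346 and 1019 for metformin against wild type. They were 664 and 1850 for calls opposite in Alport and with losartan, 238 and 1132 for Alport and metformin, and 222 and 1003 for calls shared by the drugs. For Alport vehicle against wild type they were 2549 and 3756, within 1.5 times the main count.

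The results that turned were uncalled. In Alport vehicle against wild type the lists of the thick ascending limb (median 0.003) and endoplasmic reticulum chaperones (-0.002, with the test pointing up) turned after a new quantile normalization, and adrenal cortex (0.057) without the dimmest probe sets. Col4a5 with metformin moved to 0.026 after that normalization and to 0.045 after centring, Umod with losartan to 0.035 after centring, and Slc34a1 in metformin against losartan to 0.036 after that normalization and 0.001 with array weights. The cause was not tested. Without a single sample the lowest and highest medians of lists were -0.078 and 0.043 for the thick ascending limb, -0.278 and 0.037 for chaperones, -0.046 and 0.163 for adrenal cortex (main median 0.03, mean 0.00 and a test pointing down) and -0.166 and 0.144 for skeletal muscle in Alport vehicle, and -0.873 and -0.002 for MHC class II and -0.358 and 0.007 for the interferon response with metformin. For genes they were -0.368 and 0.007 for Nphs1 with metformin, -0.382 and 0.038 for Col4a5 with losartan, -0.218 and 0.202 for Col4a5 with metformin and -0.117 and 0.013 for Umod with losartan. In metformin against losartan they were -0.213 and 0.293 for Acta2, -0.062 and 0.038 for Slc34a1, -0.065 and 0.48 for Tgfb1, -0.263 and 0.012 for Nphs1 and -0.02 and 1.855 for Lcn2.

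The labels number the samples 1 to 3 in each group, but same-numbered samples share only a number, since 0 of 18 such pairs had deviations from the group means that correlated above 0.1 (from -0.14 to 0.078), and 0 of 12 samples correlated best with their own number. With the replicate number as a block the counts were 3333, 1545, 910 and 15 for Alport vehicle, losartan, metformin and metformin against losartan, and 108 and 803 for losartan and metformin against wild type. Under the block the adjusted p of Col4a5 was 0.0776 for losartan and 0.0509 for metformin against wild type.

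Splits of the samples into other groups were counted too. With 3 samples against 3 there are 10 splits, too few for a share under 0.05. The real counts of probe sets were 3582, 1755, 1096, 10, 122 and 928 in the order above, the highest of the other splits gave 0, 0, 1, 3, 9 and 0, and 1 split, the real one, was as large in each. For lists the real counts were 24, 23, 21 and 20 and the highest others 24, 24, 21 and 14, with 2, 2, 3 and 1 splits as large. A split that mixed wild type and Alport vehicle samples called 24 lists and 0 probe sets. Under the preset correlation the count of lists therefore did not set the real grouping of these 2 groups apart, nor those of losartan or metformin with vehicle. Each other split still leaves most samples of a group on one side, so part of a real difference stays in it. Its count is not that of unchanged groups and cannot decide whether chance gave the real counts of lists. Of 100 splits of the 9 samples concerned into 3 groups, 2 gave an overlap of Alport and losartan as large as the real 1503, the other being a split with 1529 that kept the 3 Alport vehicle samples together. For Alport and metformin 1 of 100 was as large as 866 (highest other 741), and for losartan and metformin 1 of 100 was as large as 730 (highest other 5). Counts as large came only with the 3 Alport vehicle samples in the vehicle place that both comparisons share. The splits therefore speak only on which 3 of the 9 samples hold that place. Except for the split with 1529, other samples held it in part or in full. Whether such splits kept the vehicle samples together in another place was not counted. They do not test how the remaining 6 samples were grouped.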

Other observations

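Of the tests below, those of the other Ces1 genes, of the neighbours of Ces1g and of male-biased and female-biased genes were chosen only after the result was seen, and the others before. Genes lining the renal pelvis and bladder (urothelium list) were higher in Alport vehicle than in wild type, with 3 of 10 rising (5 adjusted over the list alone), among them Krt7 at 0.91 ± 0.18 and Psca at 2.58 ± 0.55 (1.91 without Alport vehicle sample 3) on the log2 scale (camera adjusted p = 8.82e-05, and adjusted p = 0.166 with an estimated correlation). The same list was lower with losartan, with 1 of 10 falling (2 adjusted over the list alone, camera adjusted p = 0.00974, and adjusted p = 0.333 with an estimated correlation), and with metformin, with 1 of 10 falling (2 adjusted over the list alone, camera adjusted p = 0.00298, and adjusted p = 0.303 with an estimated correlation). Without Alport vehicle sample 3 the camera adjusted p was 0.869 for losartan and 0.318 for metformin, and without the dimmest probe sets it was 0.0643 for losartan. A minority of clock genes rose with each drug, among them Ciart, a repressor of the clock, at 1.64 ± 0.27 with losartan and 2.09 ± 0.27 with metformin. Called or not, 13 of 17 had a log2 change above 0 with losartan and 12 with metformin (medians 0.39 and 0.21). With losartan 4 of 17 rose (4 rising and 2 falling adjusted over the list alone, camera adjusted p = 0.0245, and adjusted p = 0.196 with an estimated correlation), and the camera adjusted p was 0.0586 without Alport vehicle sample 1, 0.0501 without losartan sample 2 and 0.0545 without the dimmest probe sets. With metformin 3 of 17 rose (3 rising and 1 falling adjusted over the list alone, camera adjusted p = 0.0288, and adjusted p = 0.258 with an estimated correlation), with 0.0969 without Alport vehicle sample 1, 0.0579 after a new quantile normalization and 0.0717 without the dimmest probe sets. The hour at which kidneys were taken is not given in the labels.

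Genes of oxidative phosphorylation moved little in Alport vehicle, where 11 of 48 fell (12 adjusted over the list alone), with Uqcrc2 at -1.19 ± 0.24 and a median of -0.14 (camera adjusted p = 0.0107, and adjusted p = 0.569 with an estimated correlation). That call was lost without Alport vehicle samples 1 (camera adjusted p = 0.0856) or 3 (0.066), and after a new quantile normalization (0.63). With metformin 4 of 48 rose (8 adjusted over the list alone, median 0.19, camera adjusted p = 1.57e-05, and adjusted p = 0.337 with an estimated correlation). The median in metformin minus losartan was 0.16, with 0 called and 0 adjusted over the list alone (camera adjusted p = 0.000244, and adjusted p = 0.513 with an estimated correlation), and the camera adjusted p was 0.167 without metformin sample 3. Thick ascending limb genes rose with metformin in 4 of 13 cases (6 adjusted over the list alone, median 0.40, camera adjusted p = 6.74e-05, and adjusted p = 0.119 with an estimated correlation), while with losartan the median was 0.16 (1 rising, 1 adjusted over the list alone, camera adjusted p = 0.158). In metformin minus losartan this list had 0 called and 0 adjusted over the list alone (median 0.27, camera adjusted p = 0.000896, and adjusted p = 0.227 with an estimated correlation, and 0.0654 without metformin sample 3).

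Ces1g stood at 7.57, 5.85 and 6.23 on the log2 scale in the metformin samples and at 10.07 or higher in the other 9 samples. Signal shared with related genes was tested on Ces1d, Ces1e and Ces1f, whose median log2 change in metformin minus losartan was -0.447 (lowest -0.46), far from the change of Ces1g at -5.58, which argues against it as the cause of the whole difference. An inherited segment of another strain that changes several neighbours was tested on the 20 nearest named genes, of which 0 were called. Their median absolute change was 0.17, against a 95th percentile of 0.233 over 1960 windows of other genes. Since only 10 of 22206 probe sets were called here, 0 of 20 was likely in any case. A median also does not move when a few genes change. The test shows no broad change of the neighbours and cannot decide whether a segment changed a few of them. A variant in Ces1g itself that alters its transcript or its match to the probes stays open as untested. An effect of metformin on Ces1g is a hypothesis that the design names and that stays open beside it.

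Genes known to be higher in male than in female mouse kidney were low in Alport vehicle kidneys, with 13 of 16 measured genes (17 listed) falling and a median log2 change of -1.36, among them Cyp4a12a, Slco1a1 and Cyp2d9. With losartan 13 of the 16 rose (median 1.13), with metformin 6 rose (median 0.76), and in metformin minus losartan 2 fell, Cyp4a12a and Cyp4a12b. A lower share of proximal tubule cells would lower female-biased genes too, but the median of the 5 measured of 6 listed female-biased genes was 0.54 (95% bootstrap interval -0.197 to 2.833, which with 5 genes is the lowest and highest of them), of which 1, Abcc3, rose, so this explanation stays open, and the 34 other proximal tubule genes had a median of -0.81 with 26 falling. The median of the male-biased genes lay 0.552 below that of these other genes (permutation p = 0.0029), but these genes too were listed after many of their values had been seen, so this leaves the share of tubule cells open. Lower androgen-dependent expression may account for the pattern, and the difference of medians between male-biased and female-biased genes was -1.90 (permutation p = 0.0018), but the genes were listed after many of their values had been seen, so this cannot be told apart from a lower share of tubule cells. Both permutations shuffled genes as if they were independent, although all were measured in the same samples. Their p-values therefore do not measure the spread between samples. Of the male-biased genes 4 also belong to the proximal tubule list, and all were listed as expressed in kidney.

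The opposition of drug and disease changes was tested against what the shared Alport vehicle samples alone would give. The covariance was -0.2124 for losartan, where 100 simulations of unchanged groups gave -0.0234 to -0.0216, and -0.1604 for metformin, where they gave -0.0239 to -0.0217. It stayed at -0.142 or lower for losartan and at -0.0847 or lower for metformin when no sample was shared. The shared samples are therefore argued against as the whole source of the opposition. Transcript levels lay nearer wild type in the drug groups than with Alport vehicle. Over all probe sets, the SD of the difference from a wild type sample was 0.41 to 0.46 with losartan. With Alport vehicle it was 0.56 to 0.73, and with metformin 0.44 to 0.59, mostly below the range with vehicle. Against wild type 3582 probe sets changed with vehicle, 122 with losartan and 928 with metformin. What caused this was not tested, nor whether other traits of the kidneys lay nearer wild type.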
